A study of Mus musculus with 12 samples.

How the data were processed

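Whole retinas of control mice and of mice with a glial deletion of ABCA1 were profiled by RNA sequencing at 3 and 12 months, with 3 libraries per group. Per the labels' protocols, RNA with an integrity number above 8.0 was made into stranded poly(A) libraries and sequenced on an Illumina instrument. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 to GRCm38 and counted with featureCounts 1.6.4, and DESeq2 1.22.1 was used. The authors deposited raw counts per Entrez gene ID for each library. The strand setting of the counting, the treatment of reads with several alignments and the filters are not given in the sources used here, so genes that overlap, have an antisense partner or share reads with near-identical copies are uncertain.

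The authors also deposited a table without a header for the 12-month comparison, whose columns were read as mean normalized count, log2 fold change, standard error, Wald score, p-value and adjusted p-value. The log2 values deposited by the authors span a narrow range and were taken as shrunken. The score in the table deposited by the authors equals the log2 fold change over its standard error. Values from this table are given as the authors', and all others were computed from the counts.

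Each library had 27179 gene IDs, of which 25275 were named from a RefSeq table of the same build and a further 18 from GENCODE tables, leaving 1886 unnamed with at most 0.282% of the counts. Library totals ran from 29027099 to 30438026, and the top 10 genes took 7.75% to 8.59% of the counts. Between 60.7% and 70.2% of the counts from 1 to 20 were even numbers, against 48.6% to 50.7% of those from 101 to 400, so the reads of a pair appear to have been counted separately and a low count stands for fewer fragments than its number. The squared differences between replicate libraries of a group were 3.52 to 43.1 times the counting variance (chi-square per degree of freedom), so no library was a copy of another. Counting the reads of a pair separately would raise this ratio.

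Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were filtered with filterByExpr, which left 16475, and libraries were scaled by TMM. A quasi-likelihood model (robust glmQLFit and glmQLFTest) with 1 coefficient per group was fitted to all 12 libraries, with a common biological coefficient of variation of 0.111, and p-values were adjusted by Benjamini-Hochberg. Log2 CPM values used a prior count of 2. The contrasts were KO against control at each age, 12 against 3 months in each genotype, and the difference of the KO effects. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. Of 36 lists fixed before the data were examined, 35 had the 4 tested members needed. The 2 lists of muscle genes and of genes that escape X inactivation were written after the data had been seen.

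The genes named were chosen by a rule fixed before the data were examined. It took Abca1, then, among genes with an adjusted p below 0.05, a mean of at least 1 CPM and no overlap between groups, the 10 largest rises and falls at 12 months and the 5 largest in each other comparison. For the difference of KO effects the overlap condition was not applied. It also took from each list 2 to 4 passing members with the smallest adjusted p, or, where none passed, the 2 with the highest mean CPM. Gene models without a name were only counted. Members of the lists adjusted over the list alone, the genes at the start of chromosome 3, Y-linked genes and single muscle and lens genes were named after their values were seen.

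The model was tested on simulated counts for the 12-month KO comparison, on 16282 tested genes. It recovered 60.6% of 66 genes changed 1.5-fold, 79.1% of 67 changed 2-fold and 96.9% of 65 changed 4-fold, and of 178 calls 11 were unchanged genes and 11 were among 20 genes of a planted list raised by 0.5 on the log2 scale. The real comparison gave 35 calls, so its adjusted threshold was stricter than the simulated one. No simulated library was made to stand apart from its group. Recovery in the real data may therefore be lower. The alternatives were RLE and upper quartile factors, library sizes without genes of other tissues, DESeq2 1.42.0, limma-voom with quality weights, 2 other filters, a threshold of 0.1, only the 6 libraries compared, the replicate number as a block, 1 surrogate variable from sva 3.50.0, and each library left out. Halved counts, an estimated correlation with each library left out for the lists called, and tests without genes of other tissues, or without Xist and the start of chromosome 3, were added after the data had been seen.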

Results

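Retinal RNA was sequenced from mice in which ABCA1, a transporter that moves cholesterol and phospholipids out of cells, had been deleted in glia (KO), and from control mice. Retinas were taken at 3 months and at 12 months of age, with 3 libraries in each of the 4 groups. The 12 libraries held between 29027099 and 30438026 counts, and between 18541 and 19144 genes had a count in a library. The 12-month KO libraries had 18887 to 19144 such genes, against 18541 to 18725 in the other groups, though their totals were not higher. The cause of this group difference was not tested, and it bears on genes with low counts. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

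The targeted gene, Abca1 (Entrez 11303, chromosome 4 from 53030789 to 53159988, GRCm38), was not lower in KO retina at either age. At 3 months the mean level was 22.7 ± 3.34 CPM (SD, n = 3) in control and 26.3 ± 1.78 CPM (SD, n = 3) in KO retina. At 12 months it was 30.8 ± 2.66 CPM (SD, n = 3) in control and 36.3 ± 7.91 CPM (SD, n = 3) in KO retina. The log2 fold change was 0.21 ± 0.14 (SE) at 3 months and 0.24 ± 0.14 (SE) at 12 months, with adjusted p = 0.70 and 0.65 (edgeR quasi-likelihood test, Benjamini-Hochberg). An exact two-sided permutation test gave p = 0.2 at 3 months and p = 0.4 at 12 months, where 3 against 3 libraries allow no p below 0.1. The counts cover all exons of the gene and all cells of the retina, so they cannot check a deletion made in glia alone.

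**Figure D1:**
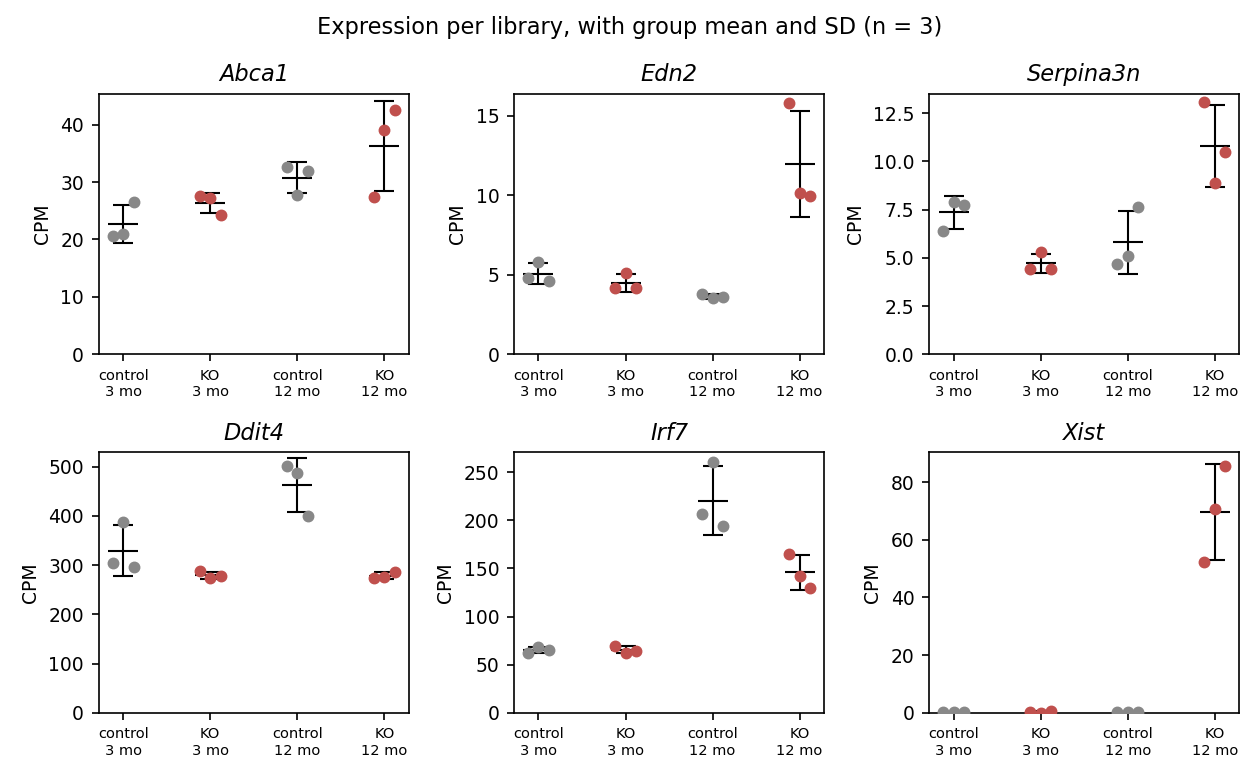
CPM (y axis, linear, from 0) of Abca1, Edn2, Serpina3n, Ddit4, Irf7 and Xist in each library (points) of the 4 groups (x axis), with the group mean and SD (n = 3). Abca1 overlaps between genotypes at 12 months, whereas the 3 KO libraries at 12 months lie above every other library for Edn2, Serpina3n and Xist.

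The first comparison asked which genes differed between KO and control retina at 12 months. Of 22 genes in the reactive glia list 2 passed, both higher in KO retina. The endothelin ligand Edn2 rose 3.29-fold from 3.64 ± 0.147 to 12.0 ± 3.31 CPM (SD, n = 3). The protease inhibitor Serpina3n rose 1.86-fold from 5.81 ± 1.62 to 10.8 ± 2.12 CPM (SD, n = 3). Whole retina does not show which cells made these RNAs. The stress-induced mTORC1 inhibitor Ddit4 was lower in KO retina, at 279 ± 7.02 against 463 ± 54.9 CPM (SD, n = 3). Its 12-month KO counts (8177 to 8452) were near those of 3-month KO (7996 to 8525). The 12-month control counts (11846 to 15000) lay above those of 3-month control (8851 to 11584), a rise with age (adjusted p = 0.0061, edgeR). The difference of the KO effects between the ages did not pass for Ddit4 (adjusted p = 0.46, edgeR). The interferon regulator Irf7 was lower too, at 146 ± 17.8 against 221 ± 35.6 CPM (SD, n = 3). A group of neighbouring genes at the start of chromosome 3 was higher, among them Pex2 and Stmn2, with fold changes of 1.69 and 1.61. In all, 35 of 16475 genes passed an adjusted p of 0.05 (edgeR quasi-likelihood test), 21 higher and 14 lower in KO, and 5 of them were gene models without a name.

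The highest rise at 12 months was that of Xist, the RNA that coats the inactive X chromosome, from 0.179 ± 0.0202 CPM in control to 69.5 ± 16.6 CPM in KO retina (SD, n = 3). The other named genes with the largest rises were Itih2 (log2 fold change 2.96), Arrdc3 (0.85), Hmgb2 (0.85), Zc2hc1a (0.82), Gsto1 (0.77) and Pex2 (0.76). Muc4, a mucin of surface epithelia, was barely detected in 12-month control and stood at 1.06 ± 0.333 CPM (SD, n = 3) in KO retina, too few control counts for a fold. In 3-month control it had 13 to 25 counts, and in 3-month KO 10 to 32. Hmgb2, a chromatin protein, went from 42.3 ± 5.85 to 76.1 ± 4.02 CPM (SD, n = 3). The largest named fall was that of the fibrillar collagen Col5a2 (log2 fold change -1.41). It had 30 to 52 counts in 12-month KO and 32 to 55 in both 3-month groups, against 95 to 128 in 12-month control. Besides Ddit4 and Irf7, the other named falls were Clp1 (-0.60), Trim67 (-0.55), Fam110a (-0.50), the growth factor signalling inhibitor Spry2 (-0.49), Erf (-0.48), the lactate transporter Slc16a3 (-0.46) and Ier3 (-0.46). Each of the 35 genes had 3 KO values that did not overlap the 3 control values. Passing the test on these same values nearly brings this about, so it adds no separate support.

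Of the reactive glia genes, 6 were higher when adjusted over the list alone, those besides Edn2 and Serpina3n being Lif, Ednrb, Cebpd and A2m. The list's median log2 fold change was 0.21, and it ran from 0.14 without control replicate 1 to 0.31 without control replicate 3. Camera called the list higher (adjusted p = 7.145e-10), with adjusted p = 0.017 with an estimated correlation. Without KO replicate 1 the median was 0.19, and the adjusted p with an estimated correlation was 0.080. None of the 16 complement genes passed over all genes, and 2 were higher when adjusted over the list alone, C4b (log2 fold change 0.64) and C1qa (0.41). Camera called the complement list higher (adjusted p = 0.014), though not without control replicate 1 or KO replicate 1 (adjusted p up to 0.082), with adjusted p = 0.23 with an estimated correlation. Of 17 bipolar cell markers none passed over all genes, and 5 were lower when adjusted over the list alone, among them the ON bipolar receptor Grm6 (log2 fold change -0.23). Camera called the bipolar list lower (adjusted p = 0.0014, median -0.12), with adjusted p = 0.055 with an estimated correlation. With 1 library left out, the bipolar median ran from -0.18 without KO replicate 2 to -0.079. The camera call with the preset correlation was kept each time, with adjusted p up to 0.048. The axon injury and stress list, of which 1 of 17 genes passed, Ddit4, was called lower (adjusted p = 0.025; 0.39 with an estimated correlation), but this call was lost without control replicate 1 or 2 or KO replicate 2 or 3 (adjusted p up to 0.18). The 13 mitochondrial genome mRNAs, none of which passed, had a median of 0.38 and were called higher (adjusted p = 0.00067), with adjusted p = 0.44 with an estimated correlation. That call rested on KO replicate 1, without which the median was 0.25 and the adjusted p 0.16. The list of 5 sex-linked genes was called higher through Xist, its only called member (adjusted p = 3.369e-19; adjusted p = 0.016 with an estimated correlation).

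Retinal ganglion cell markers were not called as a list at 12 months (23 tested, median log2 fold change -0.05, camera adjusted p = 0.63). Their only called member was Stmn2, which lies among the raised genes of chromosome 3. Astrocyte markers (median 0.02), Müller glia markers (0.02), sterol efflux genes and LXR targets (-0.03), sterol synthesis genes (0.08) and microglia markers (0.19) were not called by camera, with adjusted p = 0.72, 0.85, 0.72, 0.16 and 0.066. None of the tested members of these 5 lists passed over all genes. The highly expressed glial members Apoe (log2 fold change 0.01), Aldoc (-0.12) and Glul (-0.08) did not pass. The remaining lists were not called either, with camera adjusted p of 0.066 or more.

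The count at 12 months depended on single libraries. KO replicate 1 differed from the other 2 KO libraries of that age by 21.6 and 24.9 times the counting variance (chi-square per degree of freedom), against 5.16 between those 2. Edn2 stood at 15.8 CPM in KO replicate 1 and at 10.1 and 9.98 CPM in the others. Without that library 44 genes passed. It was 13 without control replicate 2, 15 without KO replicate 3 and 23 without control replicate 1, and Serpina3n (adjusted p up to 0.30, edgeR) lost its call under 7 alternatives, among them without control replicate 1 or 2 or KO replicate 1 or 3, and Irf7 (up to 0.093) without control replicate 2 or KO replicate 2 or 3. Edn2, Ddit4, Hmgb2, Itih2 and Trim67 kept their calls under all 21 alternatives, that library left out included, and so did Xist, Pex2 and Stmn2 under 20, and the remaining 13 of the 21 genes chosen and called lost their call under 1 or more alternatives.

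The authors' deposited table for the same 12-month comparison lists 109 genes below an adjusted p of 0.05, 59 higher and 50 lower. All 35 genes called here are among them with the same sign. In the authors' deposited table Edn2 has a log2 fold change of 0.85 and Abca1 of 0.16 (adjusted p = 0.72, DESeq2). Those values were taken as shrunken, and across 16473 genes, which are not independent replicates, they correlated with the fold changes computed here with a Pearson r of 0.69 and a Spearman rho of 0.93.

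The second comparison asked the same at 3 months. Genes of skeletal muscle contraction were lower in KO than in control retina, and genes at the start of chromosome 3 were higher. The troponin gene Tnnc2 fell from 12.9 ± 1.43 to 0.341 ± 0.216 CPM (SD, n = 3), and the skeletal actin gene Acta1 from 15.9 ± 2.12 to 2.56 ± 0.207 CPM (SD, n = 3). Tpd52 on chromosome 3 rose 1.62-fold, from 217 ± 20.6 to 351 ± 7.82 CPM (SD, n = 3). Of 16475 genes, 37 passed (edgeR quasi-likelihood test), 11 higher and 26 lower.

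The named genes with the largest fitted falls at 3 months were Tnni2, Myh1, Tnnc2, Myh2 and Ckmt2. Tnnc2 had a log2 fold change of -5.23, and no fold is given for the others, which had at most 4 counts in any 3-month KO library. A list of 29 skeletal muscle genes, written after these genes had been seen, had 20 members that fell. Tnnc2, one of them, had 378, 429 and 344 counts in the 3-month control libraries and at most 17 in any other library. The 19 lens genes had a median log2 fold change of -5.63, and 1 passed over all genes, Lgsn (-3.61), while 19 were lower when adjusted over the list alone. Lgsn had 27, 98 and 15 counts in the 3-month control libraries, and its log2 fold change ran from -4.03 to -2.44 under the alternatives. Lens genes took 0.579% of the counts in control replicate 2 at 3 months and 0.0273% or less in the other libraries, and camera's call for the list (adjusted p = 9.747e-18) had adjusted p = 0.65 with an estimated correlation, and without that library the median was -2.57 and the latter 0.0046. The largest named rises were Tagap1 (log2 fold change 0.95), Snx16 (0.79), Zbtb10 (0.69), Tpd52 (0.69) and Zfp704 (0.68), and all but Tagap1 lie at the start of chromosome 3. Mitochondrial genome mRNAs (median 0.34) and GABA and glycine receptors (0.14) were called higher by camera (adjusted p = 0.00013 and 0.038), with adjusted p = 0.65 with an estimated correlation for both, and no member of either passed. Both calls rested on control replicate 2, without which the medians were 0.09 and 0.04 and the adjusted p 0.13 and 0.24, and that of the receptors was also lost without control replicate 3. Reactive glia genes were not called (median -0.11, camera adjusted p = 0.12), nor were the ganglion cell, astrocyte, Müller glia, microglia and sterol lists. When lens, cornea, pigment epithelium, muscle and blood genes were left out of the test, 11 genes were called, and 21 were called without KO replicate 3. Control replicate 2 stood further apart than any other library. It differed from the other 2 controls of that age by 43.1 and 41.9 times the counting variance (chi-square per degree of freedom), against 4.19 between those 2. Without it 37 genes passed at 3 months, 440 with age in control and 29 for the difference of KO effects. Snx16 and Zbtb10 lost their calls without any 1 of the 3 KO libraries, Zfp704 also without control replicate 1 or 2, and Lgsn without any KO library or control replicate 2 (adjusted p up to 0.18, 0.10, 0.21 and 0.27, edgeR).

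**Figure D2:**
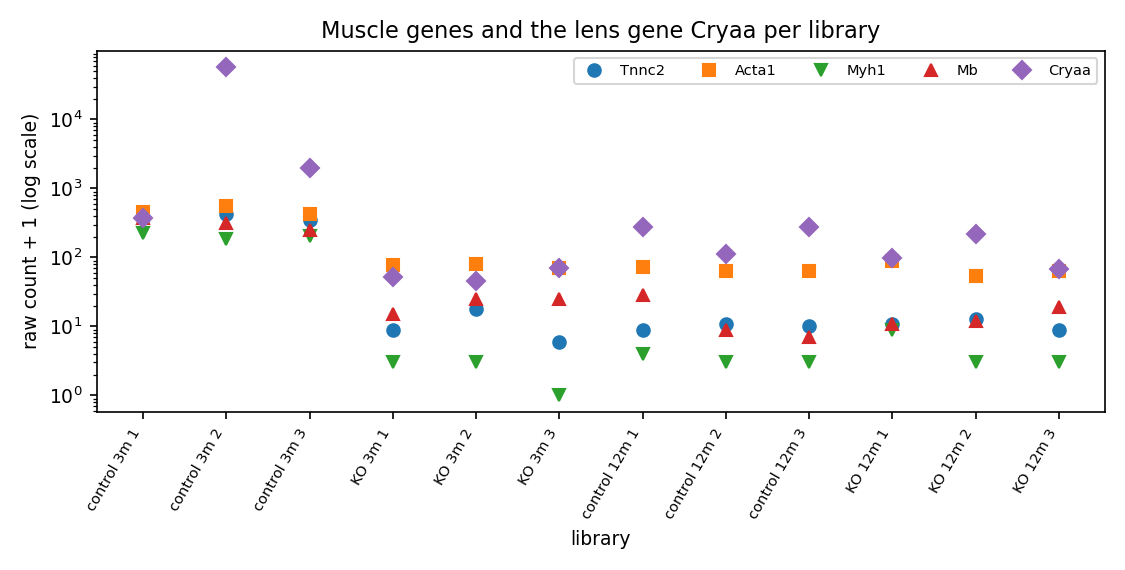
Raw count plus 1 (y axis, log scale) of the muscle genes Tnnc2, Acta1, Myh1 and Mb and of the lens gene Cryaa in each of the 12 libraries (x axis). The muscle genes are highest in the 3 control libraries at 3 months, and Cryaa reaches 57360 counts in control replicate 2 at that age.

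Few genes were called for KO against control at both ages. Across 16475 genes, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.049 and a Spearman rho of 0.23. Noise in comparisons of 3 against 3 libraries lowers such a correlation. Of the 26 genes lower at 3 months, 20 were of the muscle list, which was high in 3-month control. These values alone thus do not show that the KO effects differed between the ages. By edgeR, 5 genes were called higher at both ages, where 0.014 would be called by independent lists. The 5 genes are Pex2, Stmn2, Tpd52, Fabp12 and Impa1, all on chromosome 3 between 5218218 and 10440131. Of the 22 genes tested in that stretch, 10 were called at 3 months and 7 at 12 months, and the 19 with a mean level of at least 1 CPM had median log2 fold changes of 0.63 and 0.60. The 31 genes from 13 to 30 Mb had medians of 0.09 and 0.08.

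**Figure D3:**
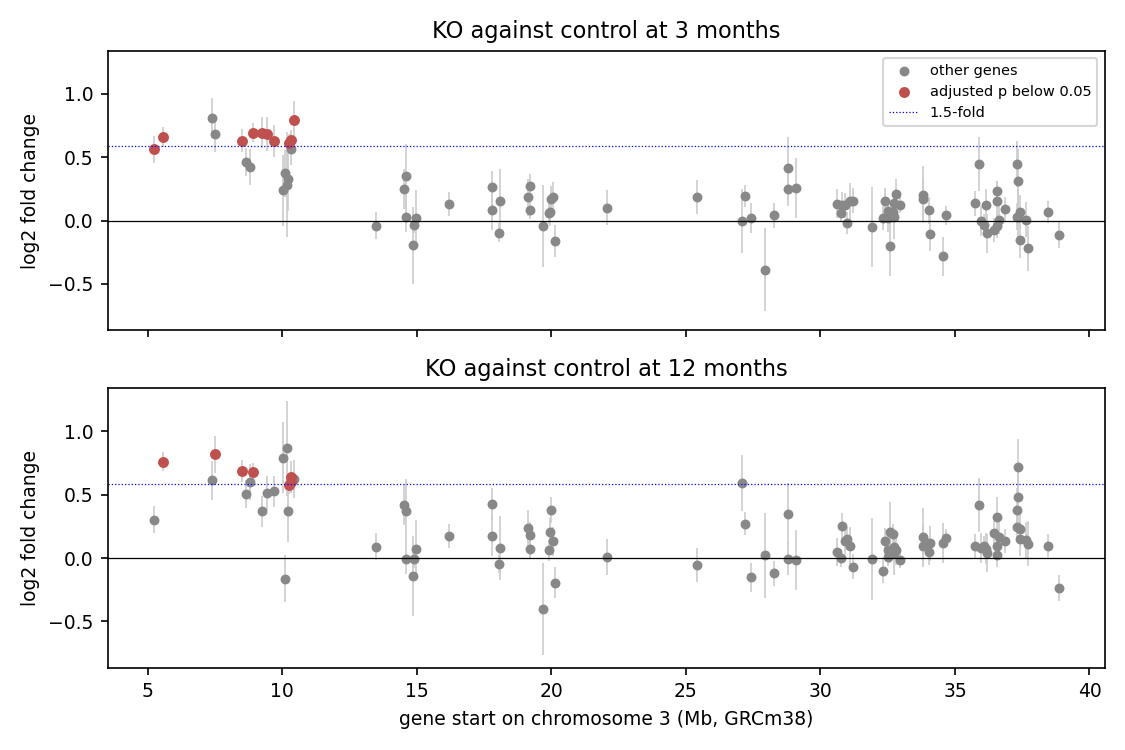
Log2 fold change of KO against control (y axis, with SE bars) of genes with a mean of at least 1 CPM by start position on chromosome 3 (x axis, Mb, GRCm38), at 3 months (top) and 12 months (bottom). Red points passed an adjusted p of 0.05 (edgeR), the dotted line marks a 1.5-fold rise, and 18 of the 19 genes that start from 5218218 to 10440131 lie above 0 at both ages.

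The third comparison followed age within each genotype. In control retina, the lists of microglia markers, antigen presentation and immediate early genes were called higher at 12 months than at 3 months. Irf7 rose 3.37-fold from 65.5 ± 3.22 to 221 ± 35.6 CPM (SD, n = 3), the class I antigen gene H2-K1 rose by 0.68 on the log2 scale from 37.7 ± 3.8 to 60.3 ± 5.51 CPM (SD, n = 3), and Nr4a1 rose 1.92-fold from 166 ± 4.24 to 319 ± 55.1 CPM (SD, n = 3). The largest named rises were Ppp1r3g, a regulator of glycogen synthesis (log2 fold change 3.22), the retinol dehydrogenase Rdh1 (2.89), Nod2 (2.87), the muscle LIM protein Csrp3 (2.80) and Cym (2.78). The named genes with the largest fitted falls were the muscle genes Myh2, Trdn, Tnni2, Tnnt3 and Myh4. The last 3 had at most 4 counts in any 12-month control library, so the order of these falls is not firm. Myh2 and Trdn had no count in control retina at 12 months and were at least 17.8-fold and 14.4-fold lower there, against a floor of 3 counts per library that covers counting error only. In total 347 genes passed (edgeR quasi-likelihood test), 230 higher and 117 lower at 12 months, 22 of them without a gene name, and 201 passed without control replicate 2 at 12 months. Of the muscle list, written after the data had been seen, 20 of 29 genes fell.

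Camera called 14 of 35 lists in control retina, 4 of them also with an estimated correlation. Those 4 were sterol synthesis and uptake (lower, adjusted p = 0.017 with an estimated correlation), microglia markers, antigen presentation and immediate early genes (each higher, adjusted p = 0.036 with an estimated correlation). With an estimated correlation the sterol, microglia and immediate early calls were lost without replicate 1 of 3-month control (adjusted p = 0.052, 0.096 and 0.12), the last also without its replicate 3 or replicate 3 of 12-month control. The antigen presentation call was lost without any of the 6 control libraries but replicate 2 of 3-month control (adjusted p up to 0.12). Of 25 sterol synthesis genes 1 passed over all genes, Insig1 (log2 fold change -0.35), and 10 were lower when adjusted over the list alone. Of 17 immediate early genes 8 rose and 1 fell, with Egr1 (0.91), Junb (0.76) and Ier2 (0.72) among the rises. Of 19 microglia markers 1 passed, C1qc (0.78), and of 22 antigen presentation genes 2 passed, H2-K1 (0.68) and Tap2 (0.58). Of 30 interferon-stimulated genes 1 passed, Irf7 (1.75), and of 16 complement genes 2 passed, C1qc and C4b (0.61). The interferon and complement calls had adjusted p = 0.20 and 0.084 with an estimated correlation. The A1 astrocyte, rod, axon injury and clock lists were also called higher, with adjusted p = 0.12, 0.40, 0.40 and 0.12 with an estimated correlation. The pericyte, pigment epithelium, lens and matrix lists were called lower, with adjusted p = 0.12, 0.28, 0.21 and 0.49 with an estimated correlation. The pigment epithelium and matrix calls were lost without replicate 2 of 3-month control (adjusted p = 0.14 and 0.56), the latter also without replicate 1 or 2 of 12-month control. The rod and axon injury calls (adjusted p up to 0.20 and 0.15) were lost without replicate 1 or 3 of 3-month control or replicate 2 of 12-month control, the rod call also without replicate 3 and the axon injury call without replicate 1 of the latter group, and the clock call without its replicate 2 (0.064). C1qc, C4b and Insig1 (adjusted p up to 0.10, 0.18 and 0.15, edgeR) each lost their call without replicate 2 of 12-month control, C4b and Insig1 also without its replicate 3, C1qc without its replicate 1, all 3 without replicate 3 of 3-month control, and C4b without replicate 1 of the latter.

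In KO retina 390 genes passed between the ages (edgeR quasi-likelihood test), 253 higher and 137 lower at 12 months, 40 of them without a gene name. The complement gene C4b rose 2.23-fold from 10.6 ± 1.27 to 23.5 ± 2.04 CPM (SD, n = 3), Edn2 rose 2.67-fold from 4.47 ± 0.550 to 12.0 ± 3.31 CPM (SD, n = 3), and the protease inhibitor A2m rose 1.97-fold from 7.15 ± 0.220 to 14.1 ± 0.907 CPM (SD, n = 3). The largest named rises included Xist (log2 fold change 7.57), Itih2 (3.25) and the retinol dehydrogenase Rdh9 (3.23), and the largest named falls were Rspo2 (-2.97), Tmprss5 (-1.41), the nicotinic receptor subunit Chrnb4 (-1.38), Neurog2 (-1.30) and Apobec2 (-1.22). Iqcm rose from a trace to 1.79 ± 0.169 CPM (SD, n = 3) and Rn7sk to 1.35 ± 0.991 CPM (SD, n = 3), with too few counts at 3 months for a fold. Rn7sk lost its call without any 3-month KO library or replicate 2 or 3 of 12-month KO (adjusted p up to 0.14, edgeR). Leaving out KO replicate 1, 2 or 3 at 3 months left 217, 190 and 187 genes, and leaving out KO replicate 2 at 12 months left 228.

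Camera called 9 lists in KO retina, 4 of them also with an estimated correlation, all higher at 12 months: reactive glia (5 of 22 passed), microglia markers (2 of 19), antigen presentation (4 of 22) and complement genes (4 of 16). Their adjusted p was 0.020 with an estimated correlation for the first 3 and 0.030 for complement. With an estimated correlation the reactive glia call was lost without replicate 1 of 12-month KO (adjusted p = 0.052), and that of complement without replicate 1 or 3 of 3-month KO or replicate 1 or 2 of 12-month KO (adjusted p up to 0.11). Besides Edn2, A2m and Serpina3n, the sphingosine receptor S1pr3 (log2 fold change 0.67) and the cytokine Lif (1.27) rose. The immediate early, interferon-stimulated, A1 astrocyte and sex-linked lists were called higher, with adjusted p = 0.056, 0.30, 0.20 and 0.056 with an estimated correlation, and the sterol synthesis list lower, with adjusted p = 0.12 with an estimated correlation. The sterol call was lost without replicate 1 or 2 of 3-month KO or replicate 2 or 3 of 12-month KO (adjusted p up to 0.14), and the A1 astrocyte call without replicate 3 of 3-month KO or replicate 1 of 12-month KO (up to 0.080). The median of the sex-linked list was -0.11, against the sign of its test. The 2 age comparisons share no library. In both, 131 genes rose where 3.53 would by independent lists, and 36 fell where 0.973 would.

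**Figure D4:**
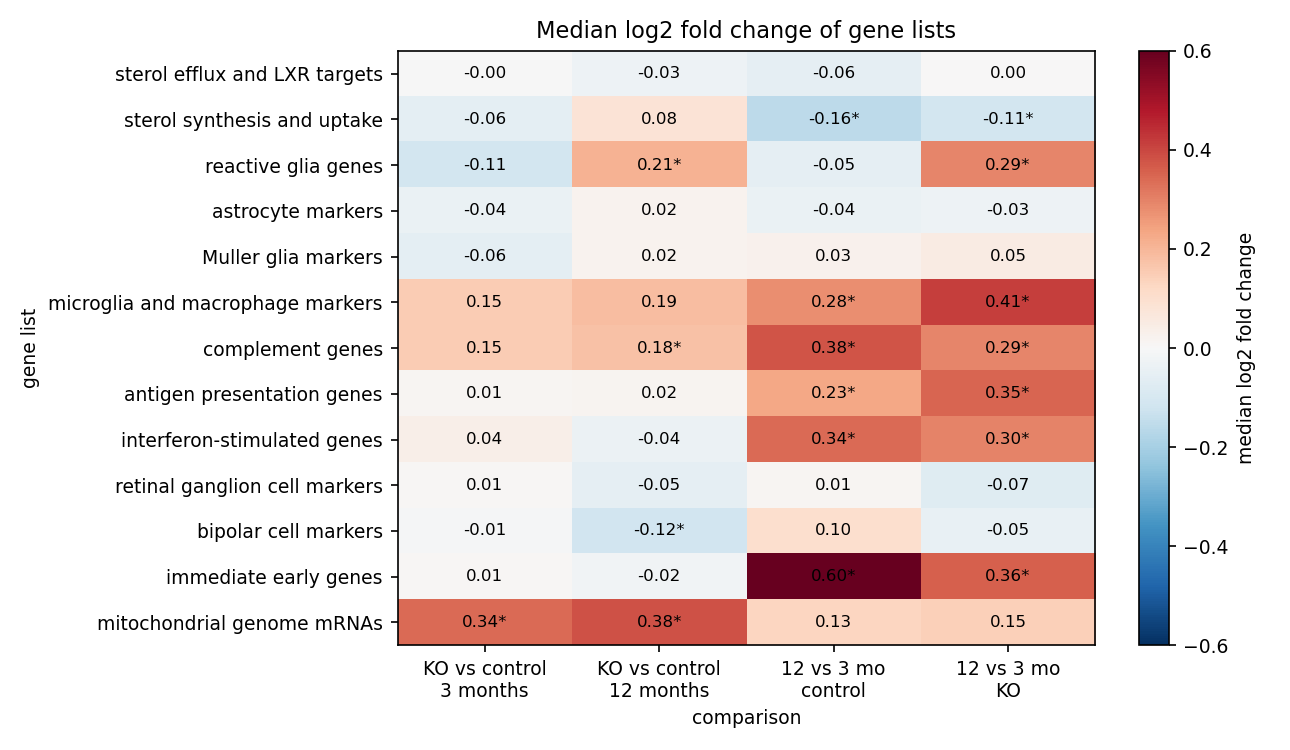
Median log2 fold change of gene lists (y axis) in the 4 pairwise comparisons (x axis), given in each cell and as colour. An asterisk marks a camera adjusted p below 0.05 with the preset correlation, and reactive glia genes have 0.21 for KO against control at 12 months and -0.11 at 3 months.

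The last comparison asked whether the KO effect differed between the ages, and Edn2 and Serpina3n were among the genes for which it did. The KO effect on Edn2 was 1.90 ± 0.26 (SE, log2) higher at 12 than at 3 months and that on Serpina3n 1.54 ± 0.26 (SE, log2) higher, with adjusted p = 0.0013 and 0.013 (edgeR quasi-likelihood test). Serpina3n had 131 to 154 counts in 3-month KO against 188 to 236 in 3-month control. Part of its difference thus came from lower KO values at 3 months. Of 16475 genes 21 passed, 18 with a higher and 3 with a lower effect at 12 months. Genes of the skeletal muscle list, which were high in 3-month control retina, made up 11 of them, and Xist, Iqcm, Tagap1 and Trim67 were among the rest. The reactive glia list was called (median 0.36, camera adjusted p = 7.925e-13; adjusted p = 0.015 with an estimated correlation), and with an estimated correlation it had adjusted p = 0.067, 0.056 and 0.057 without replicate 2 or 3 of 3-month control or replicate 1 of 12-month KO, where the medians were 0.23, 0.38 and 0.31. Serpina3n lost its call (adjusted p up to 0.071, edgeR) without replicate 1 or 2 of 12-month control, replicate 1 or 3 of 3-month KO or replicate 1 of 12-month KO, Trim67 (up to 0.11) without any 3-month KO or 12-month control library or replicate 1 or 3 of 3-month control, and Iqcm (up to 0.064) without replicate 2 or 3 of 3-month KO, while Edn2 kept its call under all 26 alternatives. Myh2 lost its call (adjusted p up to 0.48, edgeR) with halved counts and without any 12-month control library, replicate 1 or 3 of 3-month KO or replicate 2 or 3 of 12-month KO, and Tnni2 (up to 0.62) with a replicate block within age and without replicate 1 or 3 of 12-month KO.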

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

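The count of splits was set before its result was seen, while the tests of explanations in this part, and those of a list with a library left out, were chosen after. The KO effect differed between 3 and 12 months, by the interaction term of the edgeR model, for 21 genes. Of 200 possible splits of the libraries within each age 100 were counted, the real one and others drawn at random. Only the real one gave as many, with 14 as the highest of the others, so a random grouping at both ages is an unlikely source of that number. The split with 14, like every other with 8 or more genes, kept the real 3-month groups. The number thus rests in part on the 3-month difference. Because the splits regrouped both ages together, they do not show that the KO effect changed with age. The log2 difference of the KO effects was 1.90 for Edn2, 1.54 for Serpina3n, 7.96 for Xist, 6.40 for Iqcm, -1.39 for Tagap1 and -0.65 for Trim67. It was 9.82 for Myh2, 9.28 for Tnni2, 7.86 for Myh1, 5.38 for Tnnc2, 2.69 for Acta1, 2.45 for Atp2a1 and 2.04 for Des, all muscle genes. Myh2 had no count in 12-month control retina, and Tnni2, Myh1 and Iqcm had few in at least 1 group, so these fitted values are not bounds.

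By list, the median log2 difference of the KO effects was 0.36 for reactive glia genes, 0.40 for A2 astrocyte genes, 0.11 for sterol synthesis and uptake, -0.17 for bipolar cell markers, 0.15 for pericyte and smooth muscle markers, 5.89 for lens genes, 0.51 for cornea, conjunctiva and ciliary body markers and -0.0172 for sex-linked genes. Without replicate 2 of 3-month control, which held the most lens counts, the lens median was 2.93. Leaving out 1 library moved the median to between 0.23 and 0.44 for reactive glia genes, 0.25 and 0.60 for A2 astrocyte genes, 0.065 and 0.13 for sterol synthesis, -0.19 and -0.092 for bipolar markers, 0.079 and 0.30 for pericyte markers, 0.19 and 1.04 for cornea markers and -0.17 and 0.18 for sex-linked genes. The sex-linked list was called higher, against the sign of its median, through Xist. The reactive glia call was kept with an estimated correlation (adjusted p = 0.015), though not without replicate 2 or 3 of 3-month control or replicate 1 of 12-month KO (adjusted p = 0.067, 0.056 and 0.057), and the other 7 were not. With the preset correlation, calls were lost for cornea markers without replicate 2 of 3-month control, replicate 1 of 12-month control or replicate 3 of 12-month KO (adjusted p up to 0.21), for pericyte markers without replicate 2 of 3-month control (0.28), for sex-linked genes without replicate 1 or 3 of 3-month control (up to 0.11) and for sterol synthesis without 8 of the 12 libraries (up to 0.14).

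Of 29 skeletal muscle genes 20 were lower in KO than in control retina at 3 months, and 2 explanations were weighed. Of 27 muscle genes at 1 CPM or more in those libraries, 66.7% were lower in KO at 3 months by 1 or more on the log2 scale, below the 80% set for muscle tissue carried along in dissection and above the 50% that would have excluded it. Pvalb and Eno3 had log2 fold changes of -0.28 and -0.30, which did not pass, and at least 474 counts in every library, so a retinal baseline may hide a small muscle share. Neb, Ldb3, Actn3 and Casq1 did not pass either (-0.51 to 0.13), at 1.89 to 7.42 CPM in 3-month control. The counts of each in 3-month control overlapped those in the other libraries. Neb had 62 to 128 in 3-month control and 79 to 121 elsewhere, whereas Tnni2, which fell, had at most 6 elsewhere. A baseline may thus hide a muscle share in these members too. The share of members that fell depends on such baselines, so it cannot decide. A loss of muscle gene expression in KO retina would predict lower values at 12 months too, where the median was 0.12, but control levels had already fallen by then, with a median log2 change of -2.30 with age, which is the same with Myh2 and Trdn at their bounds. The explanations cannot be told apart, because no other young control group was sequenced here.

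Xist was present at 1583, 2103 and 2519 counts in the 3 KO libraries at 12 months and at 18 or fewer in the other 9. Female animals are excluded, since 4 Y-linked genes had a median log2 fold change of 0.13 at 12 months. Female RNA mixed into male samples stays open: the Y genes leave room for a share of up to 15.2%, taking 2 standard errors below their median, and no female library shows how much Xist such a share would bring. That margin replaced, after the result, 1 SD over the 4 genes (0.11), which would have left no room. A second X chromosome in male animals also stays open, with a median of 0.10 (SD over genes 0.14) for 6 genes that escape X inactivation, no higher than the 0.17 at 3 months, when Xist was not raised, and a change in Xist regulation in aged KO retina was not tested.

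Genes at the start of chromosome 3 were higher in KO at both ages, and the scaling of the libraries was not tested as a cause, since it moves every gene of a library alike. Strain variants acting gene by gene stay open: they would move genes both ways, and of the 7 expressed genes called at neither age, which did not serve to delimit the stretch, 85.7% were above 0 at both ages, between the 75% set for such variants and the 90% that would have excluded them. An extra genomic copy is another candidate explanation that stays open: 3 copies against 2 give a log2 difference of 0.585. The 10 genes called at neither age, 7 of them at 1 CPM or more, had medians of 0.40 at 3 months and 0.61 at 12 months. The first is just under the 0.4 set for a copy (0.3983). It is 0.42 without the unnamed model Gm9833 (0.37 and -0.16 at the 2 ages), with genes under 1 CPM kept. Choosing genes that missed the threshold lowers these values. The 19 expressed genes, with called ones among them, had 0.63 and 0.60, so neither set decides. A response to the loss of Abca1 cannot be told apart from an extra copy or strain variants, since the KO label and the raised stretch go together in all libraries. The lowest KO library was 0.43 above the highest control of its age. Stmn2, the ganglion cell marker that was called, lies in this stretch.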

How the results depend on the processing

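Of 8799 values of named genes under alternatives, 8524 kept their side of the threshold, 231 lost a call and 44 gained 1. None changed sign where it was called in the main or the alternative analysis, while 318 values of 112 results not called in either did. Of the named genes called, 8 of 21 at 12 months, 9 of 14 at 3 months, 26 of 38 for age in control, 26 of 43 for age in KO and 8 of 13 for the difference kept their call under every alternative. In the order KO at 12 months, KO at 3 months, age in control, age in KO and difference, the main counts were 35, 37, 347, 390 and 21. DESeq2 gave 131, 64, 579, 598 and 44, and limma-voom with quality weights 186, 79, 773, 1319 and 50. A surrogate variable, which stood at 0.91 in replicate 2 of 3-month control and at 0.087 or less elsewhere, gave 74 at 12 months. It gave 546 and 756 with age and 34 for the difference. A threshold of 0.1 gave 66 at 12 months and 560 for age in control, and no filter gave 64 at 12 months. Only the 6 libraries compared gave 198 for age in control. Without genes of other tissues, an alternative chosen after seeing the data, 11 were left at 3 months and 9 for the difference, partly because those genes were not tested, though Snx16 and Zfp704 were tested and lost their calls at 3 months (adjusted p = 0.058 and 0.089, edgeR). Leaving out 1 library gave 13 to 52, 21 to 41, 201 to 440, 187 to 367 and 14 to 29 genes. The cause was not tested for the other changes.

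Camera with an estimated correlation called 2, 0, 4, 4 and 1 lists against 6, 3, 14, 9 and 8, and fry called 3, 0 and 1 at 12 months, 3 months and for the difference. Leaving out 1 library gave 4 to 8, 3 to 7, 12 to 14, 8 to 9 and 6 to 10 lists. The correlation of the KO effects, 0.049, was -0.098 over genes called at either age and -0.013 to 0.079 without 1 library. Same-numbered libraries did not deviate together (correlations from -0.0822 to 0.138). There was thus no sign that the numbers pair them, though weak correlations cannot exclude a pairing. With a replicate block the counts were 40, 38, 317, 368 and 22, and with the block within age 42, 35, 323, 347 and 23. With the replicate block over all groups, 7, 3, 15, 10 and 8 lists were called. For the 4 pairwise comparisons 10 splits of 6 libraries are too few for a share below 0.05; 1 split of each, the real one, gave 35, 37, 347 and 390 genes, and the highest other gave 0. Genes changed 1.5-fold were recovered at 60.6% in simulated data, which had more calls (178) than the real comparison and no library that stood apart. Recovery in the real data may be lower. Halved counts, chosen after seeing the data, gave 35, 34, 341, 400 and 19 genes.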

Other observations

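The test in this part was chosen after the chromosome 3 genes had been seen. Photoreceptor lists were not called between genotypes: at 12 months the rod list had a median log2 fold change of -0.01 and the cone list of -0.08, and no member of either passed over all genes (edgeR), though 2 rod genes, Sag (0.26) and Nr2e3 (0.31), were higher when adjusted over the list alone. With age in KO retina, the cone arrestin Arr3 fell by 0.31 on the log2 scale and the rod transcription factor Nr2e3 rose by 0.34, while the ON bipolar receptor Grm6 fell in both genotypes, by 0.31 in control and 0.37 in KO. These calls were lost without single libraries (edgeR): Arr3 (adjusted p up to 0.060) without KO replicate 2 or 3 at 3 months or 2 at 12 months, Nr2e3 (up to 0.16) without any 3-month KO library or replicate 2 or 3 of 12-month KO, and Grm6 without KO replicate 3 at 3 months (up to 0.058) or, in control, without replicate 2 at 3 months or replicate 1 or 3 at 12 months (up to 0.16). The endothelial fenestration gene Plvap rose with age in both, by 0.63 and 0.72 on the log2 scale.

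Among 13892 windows of 10 neighbouring genes, ranked by the smaller of their medians at 3 and 12 months, the first lay at the start of chromosome 3, with medians of 0.64 and 0.61, and the highest smaller median elsewhere, 0.355, was in the mitochondrial genome. Tagap1 on chromosome 17 stood at 26.6 ± 1.06 CPM in 3-month KO retina against 13.8 ± 2.98, 16.9 ± 1.54 and 12.5 ± 1.51 CPM in 3-month control, 12-month control and 12-month KO retina (SD, n = 3). Iqcm was at 0.0113 CPM in 3-month KO retina and at 0.809 to 1.79 CPM in the other groups.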
